A study of Mus musculus with 9 samples.

How the data were processed

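Lung RNA of 9 male C57/BL6 mice was measured on 9 single-colour (Cy3) Agilent arrays that carry probes for long non-coding RNAs and mRNAs. The labels name 3 groups of 3 lungs, called normoxia, hypoxia and hypoxia-normoxia, from a series of 24 mice, of which 3 per group gave RNA. Oxygen levels and durations are not given in the sources used here. Per the labels' protocols, ribosomal RNA was removed and the remaining RNA was amplified with random primers.

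The deposited spot intensity values are the processed signals of Agilent Feature Extraction 11.0.1.1, background-subtracted and spatially detrended within each array, per the file headers, and their 75th percentiles differed between arrays. The median signal and median local background of each spot, also deposited as intensity, entered 1 alternative. Control classes and spot flags were taken from the deposited files as the scanner software set them. Each array held 62939 spots. Between 76.6% and 89.4% of probes were well above background, with hypoxia-normoxia replicate 3 the lowest and normoxia replicate 1 the highest. Signal over background limits the precision at dim probes, and the number of arrays limits it further. The spread of an array's probes from their group means did not follow detection throughout. Its SD was 0.48 both on hypoxia replicate 3, at 84.8%, and on hypoxia-normoxia replicate 3, at 76.6%.

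Values were computed as log2 of the processed signal minus the array's 75th percentile over all non-control probes. Spots of 1 probe were averaged, spots marked as non-uniform or as population outliers were left out, and control probes and 15 negative-control probes recognised by name were excluded. Probes well above background on at least 3 of the 9 arrays were tested: 54952 of 60915 passed, and 5 of these lacked all values in a group and were left out, which gave 54947. Differences are on this log2 scale and folds are powers of 2 of them. Where a probe was not well above background on any array of the dimmer group, the fold is a lower bound, from the brighter group's mean against the mean, per array, of the higher of the lowest signal well above background and the probe's own signal.

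Probes were paired with genes through the accession in the files and a table of mouse genes of assembly GRCm38.p6, which was used for names alone. This named 15 genes, each on 20 spots, and 15 of 15 accessions matched. The other probes carry design numbers or lincRNA names that the files do not pair with genes, so these probes are given by their identifiers. Of 28 gene lists fixed before the data were examined, 1, the erythroid list, had a measured member, Tfrc, and Pgk1 of the list of HIF target genes was on control spots alone. List tests, including those of the CC and CXC chemokines that the study's title names, were therefore not run, and no statement on chemokines is made here. Coding and non-coding probes could not be adjusted separately for the same reason.

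The test was limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes) on all 9 arrays with 1 shared estimate of the spread, two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. The comparisons were hypoxia against normoxia, hypoxia-normoxia against hypoxia and hypoxia-normoxia against normoxia, with a moderated F test for any difference among the 3 groups. An exact permutation test of 3 arrays against 3 cannot give a p under 0.1. The procedure was tested on simulated data for hypoxia against normoxia with 54947 probes: of 100 probes changed 4-fold it called 72% and of 100 changed 2-fold it called 10%, and 9.89% of the 91 calls were false.

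Genes were named by a rule fixed before the data were examined: per comparison, those past the threshold with groups that do not overlap, by size, up to 12 per direction, then filled with genes of over 1.5-fold and no overlap that did not pass, and measured members of the fixed gene lists, of which Tfrc was 1 and Pgk1, on control spots, another. Unnamed probes followed the same rule with at most 2 per direction. Items named outside the rule are marked as chosen after their values were seen. Return after hypoxia was measured, over probes past the threshold in hypoxia against normoxia, as the difference of hypoxia-normoxia from normoxia divided by that of hypoxia from normoxia. Because the comparisons share arrays, 100 sets of 9 arrays with no group difference were simulated from each probe's fitted spread.

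Per the file headers, 8 arrays came from 1 slide and 1 scan, and hypoxia-normoxia replicate 3 came from another slide and scan. The 3 normoxia arrays and hypoxia replicate 1 lay in row 1 of their slide and the other arrays in row 2, so row and group overlap almost entirely. The highest correlation between arrays was 0.987, the lowest was 0.953, and no 2 arrays held the same values. The arrays did not group fully by condition. Normoxia replicate 3 correlated at 0.977 and 0.971 with normoxia replicates 1 and 2. With hypoxia replicates 1, 2 and 3 it correlated at 0.979, 0.980 and 0.954. With hypoxia-normoxia replicates 1, 2 and 3 it correlated at 0.983, 0.980 and 0.964. Alternatives were quantile normalization, normexp background correction, another set of probes for the percentile, no filter and a stricter filter, replicate number, slide and slide row as blocks, only the groups compared, moderation with a trend, array weights, other thresholds, and leaving out each array in turn.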

Results

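Gene expression was measured in the lungs of mice kept in normal oxygen (normoxia), in low oxygen (hypoxia), or in low oxygen and then normal oxygen (hypoxia-normoxia), with 3 mice per group and 1 array per mouse. The series asks how lung transcripts differ in hypoxic pulmonary hypertension and after its reversal by return to normal oxygen. The files name 15 of the measured genes, most of them widely used reference genes, and the remaining probes are reported as counts and identifiers. Values are log2 signals relative to each array's 75th percentile, as mean ± SD of 3 arrays, and differences are given with their SE.

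Hypoxia was compared with normoxia to show what low oxygen changed. B2m, the light chain of MHC class I molecules, was 6.75 ± 0.09 in normoxia and 7.77 ± 0.37 in hypoxia, a difference of 1.02 ± 0.24 or 2.03-fold, with an adjusted p of 0.101. Gusb, a lysosomal enzyme that cleaves glucuronides, was 1.53-fold higher with a difference of 0.61 ± 0.16 and an adjusted p of 0.149. Hprt, a purine salvage enzyme, was 1.53-fold higher with a difference of 0.61 ± 0.18 and an adjusted p of 0.182. Tfrc, the transferrin receptor that takes up iron and the 1 measured member of the erythroid list, was 1.52-fold higher with a difference of 0.60 ± 0.17 and an adjusted p of 0.164. For each of these 4 genes all 3 hypoxia arrays lay above all 3 normoxia arrays, and the groups did not overlap for 7 of the 15 genes, nor for 23.6% of all tested probes, where chance gives 10%. Of the 15 genes 0 passed limma's test adjusted over all probes, while 4 had an unadjusted p under 0.05. B2m passed with normexp background correction, with an adjusted p of 0.0359, and with default and gene-by-gene array weights, and its adjusted p ran from 0.0025 to 0.668 over all settings. Gusb passed with both kinds of weights, and Tfrc and Hprt with the default weights. The default weights came from an estimate that stopped before it converged, and with them 10735 probes passed in all. Adjusted over the 15 named genes alone, these 4 genes had an adjusted p of 0.0314, a set defined by the files and not fixed before the data were examined. In mean 11 genes were higher and 4 lower, but 7 were higher and 8 lower with quantile normalization, where Ppia, Rpl13a, Tuba1b and Gapdh turned, and 9 were higher with the percentile over detected probes, where Rpl13a and Tuba1b turned. Named after their values were seen, Actb, which encodes cytoplasmic actin, differed by 0.77 ± 0.51 and Hsp90ab1, a chaperone, by -0.51 ± 0.29, both smaller than 2 SE. The 4 genes that turned were also named after their values were seen.

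**Figure D1:**
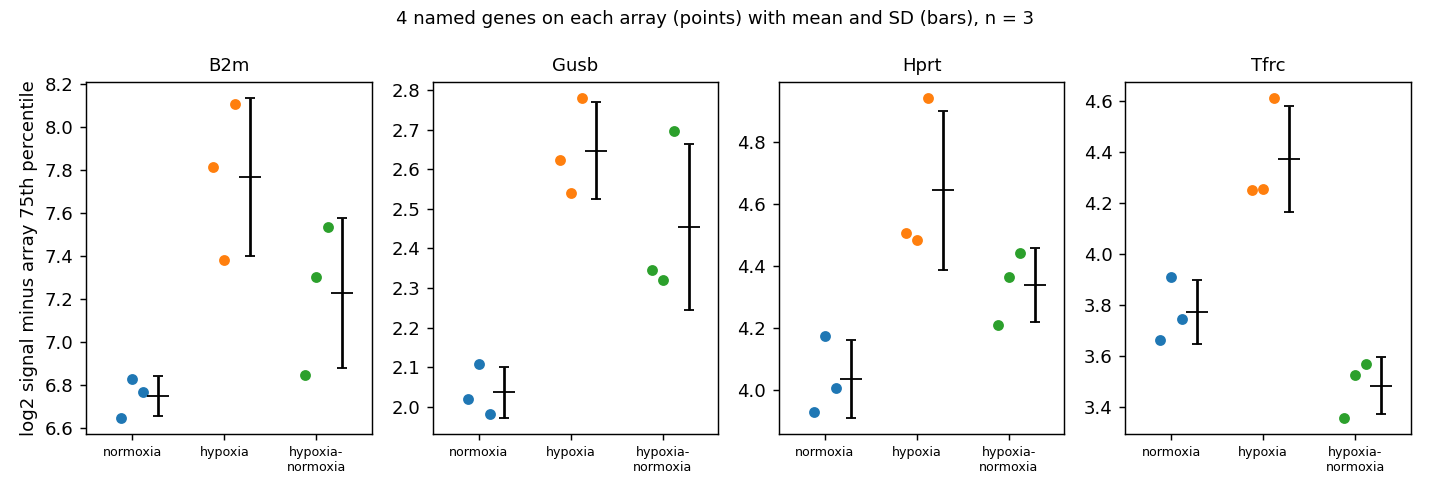
Log2 signal minus the array's 75th percentile for B2m, Gusb, Hprt and Tfrc on each array (points, 1 colour per group), with the mean and SD of each group of 3 as bars; each panel has its own vertical scale, which does not start at 0. All 3 hypoxia arrays lie above all 3 normoxia arrays for each gene, and for Tfrc the hypoxia-normoxia arrays lie below both, while 0 of the 4 genes passed the test adjusted over all probes.

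Pgk1, a glycolytic enzyme on the list of HIF target genes, was measured on control spots alone. The spot whose name ends in 3 differed by -0.21 ± 0.17 between hypoxia and normoxia and the spot whose name ends in 5 by -0.73 ± 0.24, with adjusted p of 0.586 and 0.217. The latter passed limma's test with the default array weights, whose estimate stopped before it converged, at -0.70 with an adjusted p of 0.00947. With normexp this spot differed by -0.46. It was dim, at -3.50 in hypoxia against 4.52 on the spot whose name ends in 3. The difference between these spots, which can move with RNA quality, was 7.49 ± 0.12 in normoxia, 8.02 ± 0.40 in hypoxia and 7.43 ± 0.12 in hypoxia-normoxia, with the highest value, 8.45, in hypoxia replicate 3. The exact two-sided permutation p was 0.1, the smallest possible, for hypoxia against normoxia and for hypoxia-normoxia against hypoxia, and 0.15 when adjusted over the 6 tests of the Pgk1 and Gapdh spots. For hypoxia-normoxia against normoxia it was 0.5, adjusted 0.5. The difference between the corresponding Gapdh spots, named after their values were seen, was -1.39 ± 0.05 in normoxia, -1.19 ± 0.28 in hypoxia and -1.76 ± 0.16 in hypoxia-normoxia. Its exact two-sided permutation p was 0.1 for hypoxia-normoxia against either other group, adjusted 0.15, and 0.4 for hypoxia against normoxia, adjusted 0.48.

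Across all probes, 761 of 54947 passed the threshold between hypoxia and normoxia, 398 higher and 363 lower in hypoxia, with a median size of 1.48. ASMM10P011036 rose from -2.46 ± 0.71 to 4.06 ± 0.21, which is 91.8-fold, with an adjusted p of 0.00123. ASMM10P049924 rose from -0.24 ± 0.32 to 5.08 ± 0.09, which is 40.0-fold, with an adjusted p of 7.69e-05. ASMM10P001257 was 81.1-fold and ASMM10P047539 79.3-fold lower in hypoxia, with adjusted p of 0.0184 and 0.011, and their normoxia SDs were 2.35 and 1.94. The log2 difference of ASMM10P001257 was -5.34 without normoxia replicate 1 and -7.64 without normoxia replicate 2, and that of ASMM10P047539 -5.45 and -7.36. With normexp these log2 differences were -5.39 and -5.74, and that of ASMM10P011036 was 5.93 against 6.52. Neither passed without normoxia replicate 3 or without hypoxia replicate 1, and ASMM10P001257 did not pass without hypoxia replicate 3, with adjusted p up to 0.309 and 0.245 over all settings. The count of 761 was 161 without hypoxia replicate 1, 174 without normoxia replicate 3 and 227 without normoxia replicate 1. It was 381 without hypoxia replicate 3 and 466 without hypoxia-normoxia replicate 1. Without hypoxia replicate 2 it rose to 1007, of which 642 were higher. It was 620 with the slide as a block, which nearly repeats the 622 within the slide of 8 arrays, and 279 with the 6 arrays compared. Lower probes outnumbered higher ones without normoxia replicate 1 or 2 or hypoxia replicate 1 or 3, as in 105 higher and 122 lower without normoxia replicate 1. With the slide row as a block, where the contrast rests on hypoxia replicate 1, 4 probes passed. The median size of the 761 was then 1.45 against 1.48, and their median SE 0.33 against 0.22. These probes were chosen for their difference on the same arrays, hypoxia replicate 1 among them. Their size with the block therefore cannot tell row from group.

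Among 1371 tested probes with lincRNA in their names, 1 passed between hypoxia and normoxia, where 19.6 would at the rate of the numbered ASMM10P probes (two-sided Fisher's exact test, p = 1.34e-07, adjusted p over 3 comparisons 2.01e-07) and 16.6 at that rate in probes of equal brightness. Probes are not independent replicates, and the lincRNA probes had a median residual SD of 0.56 against 0.31 for the ASMM10P probes and a median level of -3.43 against -1.71. By limma 0 passed adjusted over the lincRNA probes alone, while 104 had an unadjusted p under 0.05, where chance gives 68.6. The probe that passed, humanlincRNA0660+_P1, named after its value was seen, was 5.51-fold higher in hypoxia with an adjusted p of 0.0439, a log2 difference of 2.46 that was 1.37 with normexp. It did not pass when any 1 array other than hypoxia-normoxia replicate 2 or 3 was left out, with adjusted p up to 0.654 over all settings. The lincRNA count was 0 without any 1 of the normoxia arrays, hypoxia replicate 1 or hypoxia-normoxia replicate 1, 6 without hypoxia replicate 2, and 2 without hypoxia or hypoxia-normoxia replicate 3.

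Hypoxia-normoxia was compared with hypoxia to show what changed on return to normal oxygen. Tfrc was 4.37 ± 0.21 in hypoxia and 3.48 ± 0.11 in hypoxia-normoxia, a difference of -0.89 ± 0.17 with an adjusted p of 0.175, and with an adjusted p of 0.00846 over the 15 named genes alone. G6pd2, which encodes a form of the first enzyme of the pentose phosphate pathway and resembles its X-linked relative so that its probe may not separate them, was 1.58-fold higher with a difference of 0.66 ± 0.22 and an adjusted p of 0.321. The other genes given for this comparison, and the control spots, were named after their values were seen. Nono, a nuclear RNA-binding protein, differed by 0.65 ± 0.23, but its groups overlapped. Gapdh, a glycolytic enzyme with many pseudogenes, differed by -0.56 ± 0.22 with an adjusted p of 0.358. On its control spots Gapdh differed by -0.65 ± 0.23 and by -0.08 ± 0.18, of which the latter turned to 0.11 with quantile normalization. Pgk1 differed by -0.10 ± 0.17 on the spot whose name ends in 3, which turned to 0.058 with quantile normalization. On the spot whose name ends in 5 it differed by 0.49 ± 0.24. B2m differed by -0.54 ± 0.24, Hprt by -0.31 ± 0.18 and Gusb by -0.19 ± 0.16, so that each of these had a hypoxia-normoxia mean between the other groups' means. Of the 15 named genes 0 passed limma's test adjusted over all probes, while 4 had an unadjusted p under 0.05. Tfrc, G6pd2, Nono and Gapdh passed with default array weights, as did the Gapdh control spot that differed by -0.65. That estimate stopped before it converged, and with it 3712 probes passed in all. In mean 6 of the 15 named genes were higher and 9 lower in hypoxia-normoxia, but 8 were higher and 7 lower with quantile normalization, where Ppia and Rpl13a turned.

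In this comparison 4 probes passed, 1 higher and 3 lower in hypoxia-normoxia, while 6936 had an unadjusted p under 0.05, where 2747 would by chance. ASMM10P012543 was at least 1.67-fold higher, since it was not well above background on any hypoxia array, with an adjusted p of 0.0412. ASMM10P013477 was 15.6-fold lower and ASMM10P031147 4.34-fold lower, with adjusted p of 0.0412 and 0.0392. ASMM10P011356, named after its value was seen, differed by -1.90 with an adjusted p of 0.0412. With normexp that bound was 1.47-fold and ASMM10P012543 did not pass, with an adjusted p of 0.122, which ran from 0.00267 to 0.351 over all settings, and ASMM10P011356 differed by -1.28. All 4 had passed in hypoxia against normoxia in the opposite direction, where lists of equal length from arrays simulated with no group difference shared 2.59 on average and up to 4, because both comparisons use the hypoxia arrays, and independent lists 0.0283. The correlation of these comparisons across all 54947 tested probes was -0.54 against -0.50 in simulation. The hypoxia arrays were then dealt out so that none was shared, a test chosen after seeing the data. Over the 54773 probes with a value on every array, the correlation ran from -0.26 to -0.02 in the 6 ways. Simulation gave about 0. The value nearest to 0 came with hypoxia replicate 2 alone in hypoxia against normoxia. The simulated arrays were independent and without a slide row, so they need not show what unchanged groups of these arrays would give. The count of 4 was 0 when any 1 array other than hypoxia replicate 2 was left out, 139 without that array, and 18 with quantile normalization, 9 of them higher. It was 0 with the slide or the slide row as a block, within the slide of 8 arrays and with the 6 arrays compared. Over the 4 probes the median size was 2.23 without a block, 2.31 with the slide and 2.18 with the row, and the median SE 0.20, 0.23 and 0.22.

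Hypoxia-normoxia was compared with normoxia to show what still differed after return. Tfrc was named here as a list member, and the other genes after their values were seen. Gusb differed by 0.42 ± 0.16, B2m by 0.48 ± 0.24, Hprt by 0.30 ± 0.18 and Tfrc by -0.29 ± 0.17, and for each of these 4 genes the groups did not overlap, as for 20.6% of all tested probes, where chance gives 10%. Gapdh differed by -0.48 ± 0.22, with overlapping groups. In mean 9 of the 15 named genes were higher and 6 lower under each scaling tried. By limma 0 passed adjusted over all probes, with a smallest adjusted p of 0.364, and 1 had an unadjusted p under 0.05.

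Of all probes, 709 passed, 439 higher and 270 lower in hypoxia-normoxia, with a median size of 1.43, while at an unadjusted p under 0.05 and at least 2-fold the balance turned, with 727 higher and 1282 lower. ASMM10P033107 rose 13.2-fold with an adjusted p of 0.0078 and ASMM10P049924 rose 11.8-fold with an adjusted p of 0.00242. ASMM10P041339 was at least 24.6-fold lower, being not well above background on any hypoxia-normoxia array, and ASMM10P047539 was 72.7-fold lower, with adjusted p of 0.0199 and 0.018. The bound of ASMM10P041339 was 14.3-fold without normoxia replicate 1, 46.4-fold without normoxia replicate 2 and 7.95-fold with normexp, where the fitted log2 difference was -3.17 against -6.50 with an adjusted p of 0.0203. The log2 difference of ASMM10P047539 was -5.32 without normoxia replicate 1 and -7.24 without normoxia replicate 2. Without normoxia replicate 3 only ASMM10P049924 of these 4 passed. Neither of the lower ones passed without any 1 of the hypoxia-normoxia arrays, nor ASMM10P041339 without normoxia replicate 1 or hypoxia replicate 1. Of the 1371 lincRNA probes 0 passed by limma, where 18.3 would at the rate of the ASMM10P probes (two-sided Fisher's exact test, p = 3.36e-08, adjusted p over 3 comparisons 1.01e-07) and 13.9 at that rate in probes of equal brightness. By limma 115 had an unadjusted p under 0.05, where chance gives 68.6. As above, probes are not independent replicates, and the lincRNA probes had the larger residual SD. The count of 709 was 1 without normoxia replicate 3, 11 without hypoxia-normoxia replicate 3 and so within the slide of 8 arrays, 81 and 204 without hypoxia-normoxia replicates 2 and 1, 110 without normoxia replicate 1 and 161 without hypoxia replicate 1. The slide as a block fits hypoxia-normoxia replicate 3 alone and so nearly repeats leaving it out. With that block the count was 11, at a median size of 1.36 and a median SE of 0.23 against 0.22. It was 40 with the 6 arrays compared. The lincRNA count was 1 without hypoxia replicate 3. All normoxia arrays lay in row 1 and all hypoxia-normoxia arrays in row 2, so here row and group can be parted through the hypoxia arrays alone, and with the row as a block 0 probes passed by limma. The median size of the 709 was then 1.39, and their median SE 0.41 against 0.22. These probes were chosen for their difference on the same arrays, so that size cannot tell row from group. ASMM10P033107 differed by 3.40 ± 0.59 with that block and by 3.72 ± 0.31 without it, so its call ended with the larger SE. The difference between the Gapdh spots, which can move with RNA quality, was -1.76 ± 0.16 in hypoxia-normoxia and -1.39 ± 0.05 in normoxia. Its exact two-sided permutation p was 0.1, adjusted 0.15. That of the Pgk1 spots was 7.43 ± 0.12 and 7.49 ± 0.12, with a p of 0.5 by the same test, so the 2 readings disagreed.

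The return was measured over the 761 probes that differed between hypoxia and normoxia. Their median ratio was 0.73, between 0.68 and 0.74 on the 3 hypoxia-normoxia arrays, where 0 is a full return and 1 is none, and 188 of them had a ratio under 0.5. The 3 array values share the normoxia and hypoxia means, so their range does not measure the uncertainty of the ratio. All normoxia arrays lay in row 1, and all hypoxia-normoxia arrays and hypoxia replicates 2 and 3 in row 2. An effect of row would therefore enter both differences and could move the ratio away from a full return. Arrays simulated with no group difference gave 0.50, because the comparisons share the normoxia arrays. Over 20 simulated draws a full return gave 0.02 and no return 0.98. Leaving out 1 array gave ratios from 0.43, without hypoxia replicate 2, to 0.82, without normoxia replicate 2. No simulation was run with an array left out, so the simulated 0.50 is not a reference for these. Of the probes higher in hypoxia 176 were also called higher in hypoxia-normoxia and of those lower 175 were also called lower, where simulation gave 81.2 and 58.1 and independent lists 3.18 and 1.78, and 0 were called in opposite directions. Hypoxia-normoxia against normoxia had 1 call without normoxia replicate 3 and 11 without hypoxia-normoxia replicate 3, which caps the overlap there. Across all 54947 tested probes, not the 761 alone, the correlation of the changes was 0.59 against 0.50 in simulation. Their covariance was 0.151 against 0.0634, and probes are not independent replicates. Normoxia arrays were then dealt out, 1 to one comparison and the other 2 to the other, a test chosen after seeing the data. It used the 54773 tested probes with a value on every array. The correlation averaged 0.24 over the 6 ways, from 0.16 to 0.32, where simulation gave about 0. The covariance averaged 0.0797, from 0.0580 to 0.112, where simulation also gave about 0. The lowest of each came with normoxia replicate 2 alone. All simulated arrays here were independent, of equal spread within a probe and without a slide row. Same-number deviations of the real arrays correlated from -0.48 to 0.35. The simulated values therefore need not be what unchanged groups of these arrays would give, and the excess does not part a response from row.

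**Figure D2:**
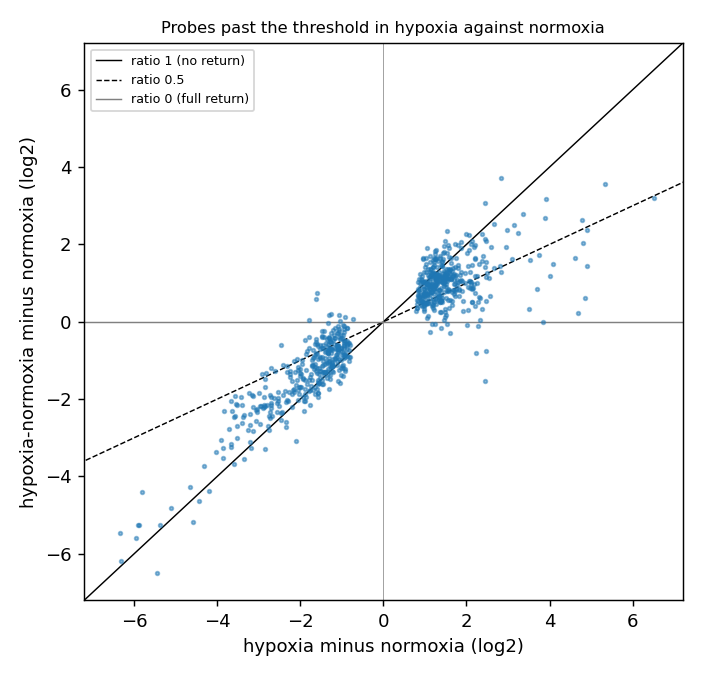
Hypoxia-normoxia minus normoxia (vertical, log2) against hypoxia minus normoxia (horizontal, log2) for each of the 761 probes past the threshold in hypoxia against normoxia (points). Lines mark ratios of 1, 0.5 and 0; the median ratio is 0.73, and 188 points have a ratio under 0.5.

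The F test found 789 probes that differed among the 3 groups. That count was 79, 483 and 37 without normoxia replicates 1, 2 and 3. It was 100 and 476 without hypoxia replicates 1 and 3 but 1084 without hypoxia replicate 2. Without hypoxia-normoxia replicates 1, 2 and 3 it was 423, 371 and 333.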

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

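Tests chosen only after the result was seen are the splits of 6 arrays, the fit with the slide row as a block, and the division of left-out probes by direction. Of 12 ERCC control probes, which no comparison used, 4 lay above the 99th percentile of the structural negative spots on all 9 arrays. Of 15 probes named as negative controls, 3 did so. Among the 4, ERCC-00062 was named after its values were seen. Relative to the 75th percentile it lay at -0.71, -0.54 and -0.58 on the normoxia arrays and at 0.13, -0.39 and 1.06 on the hypoxia arrays. On the hypoxia-normoxia arrays it lay at -0.41, -0.40 and -1.41. All 3 hypoxia arrays thus lay above all 3 normoxia arrays at this control. The cause was not tested, and the other ERCC probes were not set against the groups.

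The 761 probes that passed between hypoxia and normoxia were weighed against chance, slide row and RNA quality: the 6 arrays make 10 splits, too few for a share under 0.05, and the real one gave 761 and the highest other 97, with hypoxia replicate 3 beside normoxia replicates 1 and 2. Of 100 splits of all 9 arrays 1, the real one, gave as many as its 789 probes by the F test. The highest other gave 437, which argues against chance for the F test. Splits treat the arrays as interchangeable, though row and group overlap almost entirely, and the count was 37 without normoxia replicate 3. Chance is therefore not excluded. Of 500 probes chosen on 7 arrays and read on a left-out pair, hypoxia replicate 1, which lies in the normoxia row, kept the direction at 91% or more. Hypoxia replicate 2, whose Pgk1 spots read nearest to normoxia, kept it at 86.4% or more. Both met the bounds set beforehand, but 1 array each excludes nothing, a stricter reading adopted after the values were seen. Row and RNA quality therefore stay open. That 4 passed with row as a block decides nothing, since the median SE was 0.33 against 0.22. The median size of the 761 was 1.45 against 1.48, but they were chosen on these same arrays, so their size decides nothing either. In the pair of hypoxia replicate 3 and normoxia replicate 3, singled out after the values were seen, 47.8% of the 500 kept their direction. This was 97.2% of 109 higher but 34.0% of 391 lower probes. At the lower probes normoxia replicate 3 lay at -0.89 and hypoxia replicate 3 at -0.45 from the mean of the other normoxia arrays. The other 8 pairs kept 86.8% to 98.9% of lower probes and 220 of this pair's 500 probes were among the 761, so how many of the calls may rest on single mice is not shown, and a response to hypoxia stays open.

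The 709 probes that passed between hypoxia-normoxia and normoxia were 11 without the array on the separate slide. Of 500 probes chosen on 7 arrays, that one among them, and read on left-out pairs from the shared slide, 89.8% or more kept their direction in each of 6 pairs, which argues against the separate slide and scan as the whole cause. Slide row, which parts these groups completely, and RNA quality as the Gapdh spots read it, which was not tested here, stay open beside a lasting difference after hypoxia. The Pgk1 spots read 7.43 in hypoxia-normoxia and 7.49 in normoxia, so they did not show such a difference in quality. With row as a block 0 passed by limma, at a median SE of 0.41 against 0.22, which decides nothing about row. The median size was 1.39 against 1.43, but the 709 were chosen on these same arrays, so it decides nothing either. The 6 arrays make 10 splits, too few for a share under 0.05, and the real one gave 709 and the highest other 2.

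For the 4 probes that passed between hypoxia-normoxia and hypoxia the 10 splits are also too few for a share under 0.05, and the highest other gave 0.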

How the results depend on the processing

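Chosen after seeing the data were normexp on the median signal (the planned mean signal is not among the columns used, so that version was not run), slide row as a block, gene-by-gene array weights, and leaving out hypoxia and hypoxia-normoxia replicates 3 together. Not run, for lack of gene names, were the list tests, probes averaged per gene and the separate adjustment of coding and non-coding probes; the F test and the ratio need all 3 groups. Counts follow in the order hypoxia against normoxia (761), hypoxia-normoxia against hypoxia (4), hypoxia-normoxia against normoxia (709) and F test (789), and the cause was not tested unless given. The labels state no pairing by replicate number. Same-number deviations correlated from -0.48 to 0.35, but different-number pairs were not set beside them, so a pairing is neither shown nor excluded. With the number as a replicate block the counts were 288, 0, 134 and 162. With slide as a block, which fits hypoxia-normoxia replicate 3 alone and nearly repeats leaving it out, the last 3 were 0, 11 and 333. With row as a block the counts were 4, 0, 0 and 2, where fewer arrays inform each contrast and the SEs grew. Without both replicates 3 they were 290, 0, 0 and 50. Leaving out 1 array gave 161 to 1007, 0 to 139, 1 to 672 and 37 to 1084. With the groups compared alone they were 279, 0 and 40, from fewer arrays. Array weights gave 10735, 3712, 1513 and 10055, from an estimate that stopped before it converged and gave hypoxia replicate 1 a weight of 8.38 and hypoxia replicate 3 0.342. Gene-by-gene weights gave 2979, 201, 1225 and 2728. Unadjusted p under 0.05 with 2-fold gave 2021 (1003 higher), 1442 (562 higher), 2009 (727 higher) and 3108, so that the balance of the first and of the 709 (439 higher) turned. Hypoxia-normoxia against hypoxia gave 18 with quantile normalization (9 higher), 9 with the percentile over detected probes, 0 without filter, 56 with the stricter filter, 46 with trended moderation and 97 with normexp (53 higher), against 1 higher of 4; normexp gave 1201 by the F test. The ratio of 0.73 was 0.40 and 0.57 with the default and gene-by-gene weights, 0.67 without both replicates 3, and 0.43 to 0.82 leaving out 1 array. Of 811 values of 37 differences printed for named genes, probes and control spots, 687 kept direction and side of the threshold, 108 lost and 13 gained the call, 10 of these with the default array weights, and 3 reversed, between hypoxia-normoxia and hypoxia: Mouse-PGK1_3 with quantile normalization (0.058), and Mouse-GAPDH_5 with quantile normalization (0.11) and without hypoxia-normoxia replicate 1 (0.0058; leaving out 1 array gave -0.21 to 0.0058). Outside these, with quantile normalization Ppia, Rpl13a, Tuba1b and Gapdh turned between hypoxia and normoxia and Ppia and Rpl13a between hypoxia-normoxia and hypoxia, and Rpl13a and Tuba1b in the former with the percentile over detected probes. The lincRNA count between hypoxia and normoxia ran from 0 to 167, the highest with default array weights. Signal over background limits dim probes, most on hypoxia-normoxia replicate 3.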

Other observations

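No test here was chosen after its result was seen. Probes whose ASMM10P numbers follow each other changed together between hypoxia and normoxia: over 48306 pairs, across probes, which are not independent replicates, Pearson's r was 0.0695 and Spearman's rho 0.0539, against r from -0.0162 to 0.0151 in 1000 random pairings and 0.0139 at a distance of 100 numbers. In 56 pairs both probes had passed in the same direction and in 6 in opposite directions, where random pairings gave a mean of 5.21 same-direction pairs and 11 at most. A candidate explanation is that neighbouring numbers measure the same or related transcripts, so that the 757 numbered ASMM10P probes that passed may stand for fewer transcripts. Spots of neighbouring numbers did not lie near each other, with a median distance 100.4% of that of random pairs, which argues against a local effect of the array.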
